A study of Mus musculus with 62 samples.

How the data were processed

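Libraries of total RNA (RNeasy extraction, NEB library kits) had been sequenced from ER-Hoxb8 clones grown in RPMI medium with serum and stem cell factor, and from primary monocytes sorted out of mouse bone marrow. The deposited table gives counts, that is, raw read counts per gene, for 37620 genes. Per the submitters' processing notes, STAR 2.7.3a, HTSeq 0.6.0 and the mouse build mm9 were used, without the strand setting, the annotation release or any filter. All values are whole numbers, no 2 libraries are identical and no read is counted on mitochondrial genes. Of the gene IDs, 32897 matched names in an Ensembl-based annotation of a later build, which was used only for names and chromosomes. One column of the table, for the progenitors of a further clone, has no sample in the labels and was not used here.

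Samples were grouped by their titles and source names. The titles mark the 2 libraries of a clone as Plus and Minus; the source names give the former as granulocyte-monocyte progenitors and the latter as monocytic cells. The clone number paired them. Clones 1 to 13 and clones 15 to 25 were treated as 2 sets once the totals had shown much shallower monocytic libraries in the latter (a median of 3.18 against 26 M counts). The labels name no batch.

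Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM factors, and 2-sided quasi-likelihood F tests were used, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The paired comparison of 48 clone libraries had the clone as a block, and the clone effect was tested on the same fit as all clone terms together. The 6 libraries of classical, intermediate and nonclassical monocytes were fitted together, as were the 8 libraries of the classes, so that groups of 2 libraries share 1 estimate of spread (3 and 4 residual degrees of freedom). The biological coefficient of variation was 0.384 among clones, 0.814 among the subsets and 0.377 among the classes. CPM values are TMM-scaled, and log2 CPM used a prior count of 2.

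Correlations across clones were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, with 1e+05 permutations of the clone pairing, 2-sided for genes and scores and 1-sided for the mean profile correlation. The smallest p they can give is 1e-05. For the set-centred values the mean of each clone set was removed in each state and clones were permuted within sets. The score of a list is the mean over its genes of log2 CPM standardised over clones within a state. A class score used up to 100 genes with the smallest p among those higher in the class.

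In the comparisons between groups, 26 gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists within each comparison, and again with an estimated correlation. Stromal and endothelial genes were too few among the clones, which leaves 25 lists there. Members were counted at the threshold over all genes and adjusted over the list alone. The lists, the comparisons, the tests, the alternatives first planned and the rule for naming genes were fixed before the data were examined.

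By that rule, Hoxb8, Kit, Cd34, Csf1r, Ly6c2, Ccr2, Cx3cr1, Nr4a1 and Mpo were always to be named. In the paired comparison it took the 10 higher and 10 lower genes with the largest change among those past the threshold, with a mean log2 CPM of at least 4 and the same direction in all 24 pairs. It took 8 higher and 8 lower genes per subset comparison (mean log2 CPM of at least 3, groups that do not overlap) and 6 higher and 4 lower genes per class. For clones it took the 12 genes with the largest SD over clones that passed both the clone effect and the correlation test. Each list added up to 3 members past the threshold and the most expressed member that did not pass. Predicted genes and pseudogenes were skipped, and some named genes were left out for length.

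On simulated counts with the depths and spread of these libraries, the paired fit found 88.1% of 2-fold changes, the nonclassical comparison 0% of 4-fold and 32.3% of 16-fold changes, and the class 2 comparison 33.8% of 2-fold and 64.2% of 4-fold changes. Unchanged genes made up 1.9%, 9.09% and 10.8% of the calls of these 3 fits. The correlation tests were tried on normally distributed values of equal spread, not on counts, and without differences in depth. There a true correlation of 0.8 over 24 clones was found in 98% of genes and one of 0.6 in 59.5%. In the same simulation, genes that differed between the clone sets and were otherwise uncorrelated were called in 89.5% of cases by the pooled test and in 0% when centred on the set. These rates need not hold for libraries of unequal depth. Near-identical gene copies (Stfa1, Chi3l3, Hba-a1 and Hba-a2, Hspa1a and Hspa1b, Lyz1 and Lyz2, Ly6c2) share reads, so their counts are uncertain. Alternatives were DESeq2 size factors, DESeq2 1.42.0 itself, no filter or a minimum count of 50, a prior count of 0.5, Spearman's rho, residuals on the log2 total count, all 14 primary libraries in 1 fit, a block on the replicate number and leaving out single libraries or clones. Splicing, allele-specific counts and the reads themselves were not analysed here.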

Results

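RNA was sequenced in bulk from 62 mouse samples. Of these libraries, 48 came from 24 clones of ER-Hoxb8 cells, granulocyte-monocyte progenitors of the bone marrow that an estrogen-dependent Hoxb8 fusion protein keeps dividing in culture, with 1 library from the progenitor state and 1 from the monocytic state of each clone. The other 14 libraries came from primary bone marrow monocytes sorted by flow cytometry, 2 each of classical, intermediate and nonclassical monocytes and 2 each of 4 populations named class 1 to class 4. The labels give neither the gates of the sorts nor the definition of the classes, and they put no clone in a class. Total counts per library (M, mega) ran from 12.6 to 47.3 M in the progenitors and from 22.9 to 34.5 M in the monocytic cells of clones 1 to 13. In clones 15 to 25 they ran from 0.362 to 16.5 M and from 1.83 to 9.12 M. The lowest total, 0.362 M, was that of the clone 21 progenitors, and the next lowest progenitor library held 3.25 M. The primary libraries held 21.2 to 35 M counts, and 11106 to 17458 genes were detected per library. The labels do not say whether replicates came from separate animals or cultures, so the edgeR p-values measure only the spread between these samples. Those of camera set the genes of a list against the other genes. Those of permutations test the pairing of clones or the direction of differences within clones. None can be taken to cover the spread between animals.

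The monocytic cells of each clone were compared with its own progenitors to ask what changes as the cells mature. S100a8 (ENSMUSG00000056054) and S100a9, the subunits of calprotectin, rose by 10.06 (SE 0.927) and 9.94 (SE 0.899) on the log2 scale, S100a8 from a mean of 239 ± 665 to 18400 ± 14300 CPM (counts scaled to a common library total; SD, n = 24 clones in each state). Ngp, Camp and Ltf, which encode proteins of the secondary granules of neutrophils, rose by 9.89 (SE 1.06), 9.67 (SE 0.948) and 9.54 (SE 1.08), and Cybb, the catalytic chain of the phagocyte NADPH oxidase, by 8.6 (SE 0.797). Progenitors started from uneven levels. Split at a gap sought after the data were seen, S100a9 averaged 7.73 log2 CPM in progenitors of 11 clones and 0.89 in 13. Their monocytic cells averaged 14.57 and 13.17. Ngp averaged 6.76 in progenitors of 9 clones and −0.93 in 15. Camp, Chi3l3, Stfa1 and Olfm4 were split as well. The changes given for such genes average over both starting levels. Cd34 (ENSMUSG00000016494), a surface sialomucin of immature blood cells, fell by 5.99 (SE 0.252), from 2380 ± 773 to 42.6 ± 27 CPM, and Angpt1, a ligand of the receptor Tie2, fell by 7.13 (SE 0.327). Csf1r (ENSMUSG00000024621), the receptor for the monocyte growth factor M-CSF, rose by 6.66 (SE 0.603), from 19.9 ± 26.1 to 947 ± 667 CPM.

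In all, 9132 of 11614 tested genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 4476 upward and 4656 downward. Of these, 4613 changed at least 2-fold, 2434 upward and 2179 downward. The 20 genes that the naming rule picked for this comparison moved the same way in all 24 pairs, with adjusted p from 2.17e-18 to 6.57e-09. Besides those above they were Chi3l3, Stfa1, Olfm4 and Apoc2 among the increases and Emid1, Eltd1, Ctla2a, Spns2, Cpa3, Nrgn, Gpr56 and Slc45a3 among the decreases. Among the genes named in advance, Ly6c2, the surface marker of classical monocytes, rose by 6.69 (SE 0.908), and Cx3cr1, the fractalkine receptor, rose by 4.76 (SE 0.415). Nr4a1, a nuclear receptor needed by nonclassical monocytes, rose by 2.08 (SE 0.236). Kit, the receptor for stem cell factor, fell by 1.85 (SE 0.168), Mpo, the granule peroxidase, by 1.91 (SE 0.612) and Ccr2, the chemokine receptor for marrow exit, by 1.08 (SE 0.235). Hoxb8 counts rose by 0.7 (SE 0.23, adjusted p = 0.00738) and were higher in the monocytic library in 16 of 24 pairs. They did not pass without the pairing by clone (0.22). Their change was 1.29 in clones 1 to 13 and 0.03 in clones 15 to 25, a difference with an adjusted p = 0.0142. These counts may take in reads of the introduced Hoxb8 fusion, which were not separated from those of the cells' own gene. Clones 15 to 25 alone gave 6070 changed genes and clones 1 to 13 alone gave 9645.

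Gene lists fixed in advance were tested with camera, which asks whether a list's genes move more than the other genes. Of 18 tested regulators of progenitors and stem cells, 16 fell and 2 rose (adjusted p = 1.82e-10, and 0.0113 with an estimated correlation). Flt3, a cytokine receptor of early progenitors, fell by 8.02 (SE 0.28) and Sox4 by 5.23 (SE 0.269). All 17 tested ribosome biogenesis genes fell (adjusted p = 3.01e-10; adjusted p = 0.186 with an estimated correlation), among them Dkc1 (−3.13, SE 0.182) and Nop58 (−2.68, SE 0.189). Of 26 cell cycle genes 19 fell and none rose (adjusted p = 0.0254; adjusted p = 0.673 with an estimated correlation). The replicative helicase gene Mcm7 fell by 1.81 (SE 0.234), while the proliferation marker Mki67 did not pass the test (log2 fold change 0.19, SE 0.249); it rose by 0.72 in clones 1 to 13 alone and was at −0.43 in clones 15 to 25 alone, where it did not pass (adjusted p = 0.0521 for the difference between the sets). All 20 genes of monocyte differentiation rose (adjusted p = 1.22e-11; adjusted p = 0.0848 with an estimated correlation), as did all 6 NADPH oxidase genes (adjusted p = 2.03e-06, and 0.0374 with an estimated correlation). These 2 lists include Lyz2, the monocyte lysozyme (6.65, SE 0.401), and the oxidase subunits Cyba (2.99, SE 0.146) and Ncf1 (2.85, SE 0.134).

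Receptors and digestive enzymes of phagocytes rose together. All 16 phagocytic and scavenger receptors rose, among them the complement receptors C5ar1 (7.79, SE 0.591) and C3ar1 (6.63, SE 0.624) and the scavenger receptor Msr1 (6.29, SE 0.606), with an adjusted p = 1.89e-06 (adjusted p = 0.186 with an estimated correlation). Of 22 lysosomal genes 21 rose, including the cathepsin gene Ctsb (4.46, SE 0.272), and none fell, with an adjusted p = 1.45e-08 (adjusted p = 0.186 with an estimated correlation). Of 16 pattern recognition receptors 15 rose and 1 fell (adjusted p = 4.83e-07; adjusted p = 0.177 with an estimated correlation), with Tlr7, a sensor of RNA, at 6.39 (SE 0.454). Interferon-stimulated genes rose in 20 of 21 cases and fell in 1 (adjusted p = 9.45e-05; adjusted p = 0.349 with an estimated correlation). Inflammatory cytokines and NF-kB targets rose in 11 of 13 cases and fell in 1 (adjusted p = 0.00015; adjusted p = 0.186 with an estimated correlation), Il1rn, the interleukin-1 receptor antagonist, by 6.08 (SE 0.37). Immediate early and heat shock genes rose in 12 of 15 cases and fell in 3 (adjusted p = 0.00015; adjusted p = 0.186 with an estimated correlation), and migration and adhesion genes rose in 12 of 16 and fell in 2 (adjusted p = 0.00468; adjusted p = 0.225 with an estimated correlation).

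Markers of several mature cell types rose in the same bulk libraries, which cannot tell whether single cells carried them together. All 18 tested neutrophil genes rose (adjusted p = 1.62e-07; adjusted p = 0.186 with an estimated correlation), among them Cd177, a surface protein of neutrophils (8.65, SE 0.557), and Cxcr2, a neutrophil chemokine receptor (5.25, SE 0.36). Of 15 classical monocyte genes 11 rose and 3 fell (adjusted p = 0.00546; adjusted p = 0.247 with an estimated correlation), and of 16 nonclassical genes 12 rose and 2 fell (adjusted p = 0.00536; adjusted p = 0.195 with an estimated correlation). F13a1, a coagulation factor subunit of classical monocytes, did not pass (0.35). Tissue macrophage genes rose in 7 of 8 cases and fell in 1 (adjusted p = 0.023; adjusted p = 0.273 with an estimated correlation), Mrc1, the mannose receptor, by 5.57. The remaining lists did not pass camera. They were primary granule genes (2 of 11 higher and 5 lower, adjusted p = 0.566), antigen presentation by MHC class II (7 of 11 higher and 4 lower, 0.104), glycolysis (9 of 14 higher and 2 lower, 0.109), cholesterol synthesis (5 of 17 higher and 8 lower, 0.605), dendritic cell (2 of 5 higher and 3 lower, 0.201) and mast cell, basophil and eosinophil genes (3 of 11 higher and 6 lower, 0.576). Erythroid and megakaryocyte genes (0 of 6 higher and 3 lower, adjusted p = 0.0662), T and NK cell genes (1 of 3 higher and 1 lower, 0.86) and B cell genes (2 of 4 higher and 2 lower, 0.592) did not pass either. The B cell list had a median change of 0.07 but a mean of −1.27 with camera downward. Adjusted over the list alone, the cell cycle list had 18 lower members and every other list kept the counts given.

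**Figure D1:**
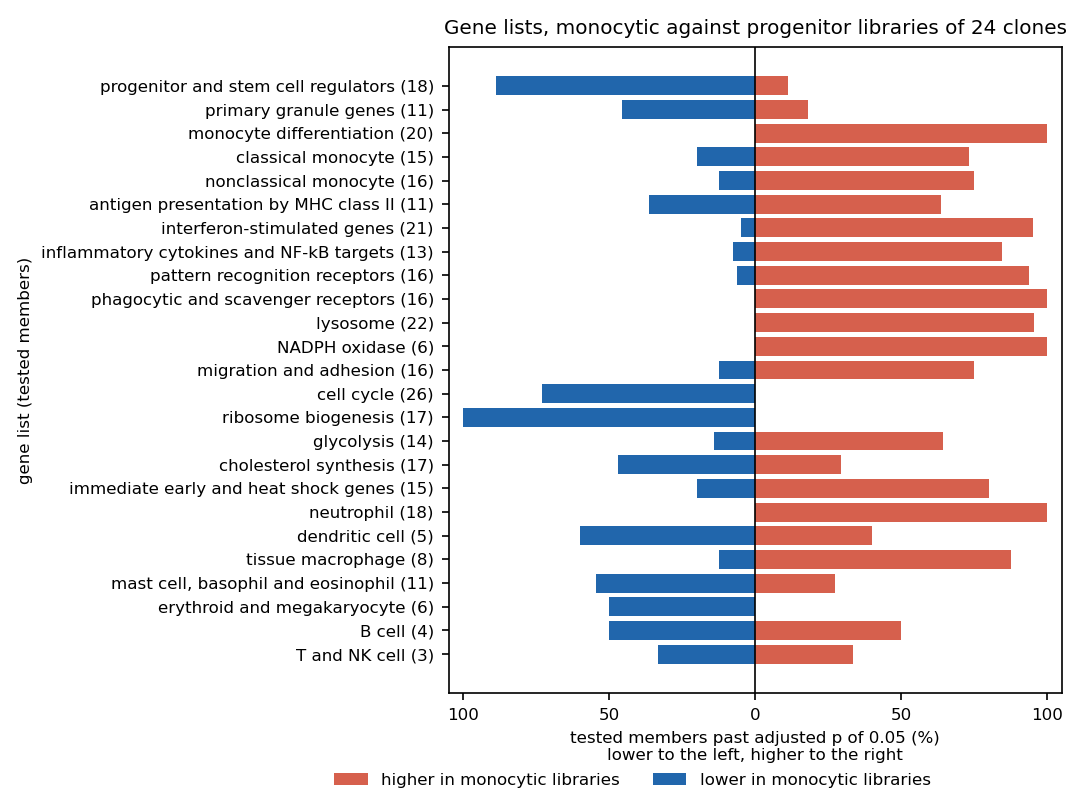
Share of the tested members of each gene list (in percent, number tested in brackets) that were higher or lower in the monocytic than in the progenitor libraries of the 24 clones at an adjusted p under 0.05. All 20 monocyte differentiation and all 18 neutrophil genes lie on the higher side, and all 17 ribosome biogenesis genes on the lower side.

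The cultured cells were set beside primary classical monocytes. Across 11614 genes, the Spearman correlation with the mean of the 2 classical libraries was 0.714 (SD 0.022, n = 24) for progenitors and 0.814 (SD 0.032, n = 24) for monocytic cells. It was higher in the monocytic library of 23 of 24 clones, by a mean of 0.1 (SD 0.036; 2-sided sign-flip permutation p = 1e-05, the smallest these permutations can give). The mean gain was 0.106 in clones 1 to 13, with 13 of 13 higher, and 0.093 in clones 15 to 25, with 10 of 11 higher. The gain was not confined to classical monocytes: with the nonclassical libraries as the reference the correlation went from 0.656 (SD 0.027) to 0.729 (SD 0.027), higher in 24 of 24 clones by a mean of 0.073. These are correlations across genes, and genes are not independent replicates. Culture and sorting differ between the clones and the primary cells, so cell type and origin are confounded here.

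The title of the series asks whether differences between monocytes are fixed, and the pairing by clone lets this be measured as the resemblance of a clone's progenitors to its own monocytic cells. After the mean of each state was removed, the progenitor and monocytic profiles of 1 clone correlated with a mean r of 0.236 across genes (SD 0.129, range −0.045 to 0.498, n = 24 clones). Pairings permuted between clones gave a mean of 0.006 (1-sided permutation p = 1e-05). In 10 of 24 clones the progenitor library correlated best with its own monocytic library. The mean was 0.343 in clones 15 to 25 (permutation p = 1e-05; 10 of 11 best with their own) and 0.066 in clones 1 to 13 (permutation p = 0.0317; 2 of 13). With each library centred on its own set of clones the mean was 0.193 (permutation p = 1e-05). Here 1e-05 is again the smallest p the permutations can give.

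**Figure D2:**
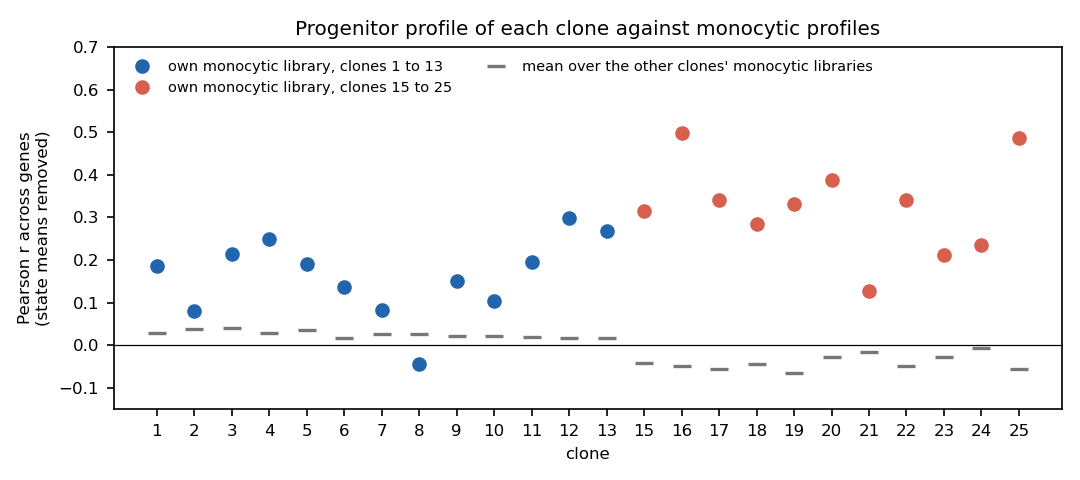
Pearson r across genes between the progenitor profile of each clone and its own monocytic profile (points, coloured by clone set), with the mean r to the other clones' monocytic profiles (grey bars), after removal of each state's mean. The values for a clone's own pair run from −0.045 in clone 8 to 0.498 in clone 16.

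Gene by gene, 1357 of 11614 genes differed among clones beyond the state (edgeR quasi-likelihood F test of the clone terms; 3161 at an unadjusted p under 0.05), 36 within clones 1 to 13 and 387 within clones 15 to 25. The progenitor level of 965 genes correlated with the monocytic level over the 24 clones at an adjusted p under 0.05, 946 positively and 19 negatively, out of 11614 relations computed. Of these 965 genes, 716 also showed a clone effect. Centred on the clone set and permuted within sets, 133 genes passed, 119 of them among the 965, while clones 15 to 25 alone gave 71 and clones 1 to 13 alone gave 0 (952 at an unadjusted p under 0.05). None of the 9 genes named in advance, Hoxb8 with its possible reads of the fusion included, passed the correlation test. The lowest adjusted p among them was 0.0642 for Ly6c2, whose r was −0.54 (permutation p = 0.00611; rho −0.59, permutation p = 0.00295; −0.42 without the 2 farthest clones; −0.6 and −0.47 in the 2 sets).

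Of the 12 genes named for the size of their clone differences, 6 passed both pooled and set-centred. Lrrk2, a leucine-rich repeat kinase, had r = 0.86 (permutation p = 1e-05, adjusted p = 0.00147) and rho = 0.72 (permutation p = 0.00011), with r = 0.61 in clones 1 to 13 and 0.95 in clones 15 to 25. Tns1, an adaptor of integrin adhesions, had r = 0.85 (permutation p = 1e-05, adjusted p = 0.00147) and rho = 0.63 (permutation p = 0.0011), with 0.79 and 0.92 in the 2 sets. Bmpr1a, a receptor for bone morphogenetic proteins, had r = 0.84 (permutation p = 4e-05, adjusted p = 0.00292) and rho = 0.66 (permutation p = 0.00056), with 0.81 and 0.85. Cln8, an export factor for lysosomal enzymes, had r = 0.82 (permutation p = 8e-05, adjusted p = 0.00458) and rho = 0.61 (permutation p = 0.00216), with 0.53 and 0.92. Spint2, an inhibitor of serine proteases, had r = 0.83 (permutation p = 7e-05, adjusted p = 0.00421) and rho = 0.56 (permutation p = 0.00546), with 0.51 and 0.88. Without the 2 clones farthest from the median, r was 0.72 for Lrrk2, 0.62 for Tns1, 0.73 for Bmpr1a, 0.52 for Cln8 and 0.49 for Spint2. For these 5 the adjusted p centred on the set lay between 0.00528 and 0.0235. With rho, Spint2 (adjusted p = 0.0863) and Cln8 (0.0535) did not pass, and on residuals of the log2 total count Tns1 did not (0.148). Sec24d, Cd24a, Padi4, Man1a and Ptgds did not pass when centred on the set, with adjusted p from 0.0616 to 0.235. Their r changed little, from 0.83, 0.71, 0.58, 0.8 and 0.57 pooled to 0.83, 0.65, 0.69, 0.74 and 0.6 centred. For Ifi27l1 and Malat1 the clones fell into separate clusters, so no pooled r is given. Ifi27l1 passed both ways (adjusted p = 0.00147 pooled and 0.0342 centred), and Malat1 passed only pooled (0.0304 and 0.631).

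Scores of the 25 lists were also compared between states, and 6 correlated over the 24 clones at an adjusted p under 0.05. The highest r was that of the glycolysis genes (r = 0.73, permutation p = 4e-05, adjusted p = 0.001; rho = 0.75, permutation p = 4e-05; 0.74 without the 2 farthest clones). It was 0.2 in clones 1 to 13 and 0.41 in clones 15 to 25, and the adjusted p was 0.307 centred on the set. The mast cell, basophil and eosinophil score passed with r both pooled and centred, but not with rho (r = 0.65, permutation p = 0.00038, adjusted p = 0.00317; rho = 0.49, permutation p = 0.0161, adjusted p = 0.067; 0.56 without the 2 farthest clones; centred r = 0.71, adjusted p = 0.0242). Its r was 0.03 in clones 1 to 13 and 0.88 in clones 15 to 25. The neutrophil score did not pass pooled, but it did when centred on the set (r = 0.64, permutation p = 0.00226, adjusted p = 0.0282) and in clones 15 to 25 alone (adjusted p = 0.00612). Its pooled r was 0.46 (permutation p = 0.0235, adjusted p = 0.0839; rho = 0.25, permutation p = 0.236; 0.32 without the 2 farthest clones), with −0.34 in clones 1 to 13 and 0.86 in clones 15 to 25. The NADPH oxidase, cholesterol synthesis, dendritic cell, and erythroid and megakaryocyte scores passed pooled (r from 0.52 to 0.68) and not when centred on the set (adjusted p from 0.136 to 0.669), where r was 0.65, 0.34, 0.46 and 0.14. In clones 1 to 13 and clones 15 to 25 their r was −0.07 and 0.7, 0.54 and 0.21, 0.19 and 0.65, and −0.56 and 0.4, in that order, so the NADPH oxidase and erythroid scores had opposite signs in the 2 sets. With rho the cholesterol synthesis score passed (adjusted permutation p = 0.0141). The NADPH oxidase, dendritic cell, and erythroid and megakaryocyte scores did not (0.0644 each).

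Nonclassical monocytes were compared with classical monocytes to place the sorted subsets. Ly6c2, the marker on which classical monocytes are usually sorted, fell from 2720 ± 316 to 21.1 ± 5.72 CPM (SD, n = 2 libraries each; log2 fold change −6.97, SE 0.362), and F13a1 fell by 5.74 (SE 0.406), from 4990 ± 283 to 92 ± 47.7 CPM. Fn1, fibronectin, fell by 6.98 (SE 1.17) and Ccr2 by 1.92 (SE 0.214). Nr4a1 rose by 3.05 (SE 0.159), from 481 ± 9.66 to 3870 ± 628 CPM, and Cd300e, an activating receptor of nonclassical monocytes, by 9.95 (SE 0.657). C1qb, a chain of complement C1q, rose by 8.36 (SE 0.333), from 1.11 ± 0.00624 to 353 ± 60 CPM, and the B cell gene Cd79a by 7.41 (SE 0.285), from 4.35 ± 0.73 to 717 ± 29 CPM. Csf1r (0.38) and Cx3cr1 (0.47, SE 0.197) did not pass.

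Of 13944 tested genes 811 changed (edgeR quasi-likelihood; 3260 at an unadjusted p under 0.05), 406 upward and 405 downward. The nonclassical list had 17 of 20 members higher and none lower (adjusted p = 3.4e-20; adjusted p = 0.0681 with an estimated correlation), including Itgax (5.45) and Fcgr4 (4.84), surface receptors of patrolling monocytes, and Cd36, a fatty acid receptor (6.01, SE 0.196). The classical list had 5 of 16 members lower (11 adjusted over the list alone; adjusted p = 6.53e-10, and adjusted p = 0.0681 with an estimated correlation). MHC class II genes were higher in 10 of 16 cases (11 adjusted over the list alone; adjusted p = 2.82e-14, and adjusted p = 0.0681 with an estimated correlation), with H2-Ab1 rising from 126 ± 3.02 to 8570 ± 169 CPM. Cell cycle genes fell in 13 of 26 cases (21 adjusted over the list alone; adjusted p = 8.13e-19, and adjusted p = 0.118 with an estimated correlation), Mki67 by 3.23 (SE 0.216). Immediate early and heat shock genes rose in 4 of 16 (9 adjusted over the list alone; adjusted p = 1.33e-05, and adjusted p = 0.44 with an estimated correlation). No interferon-stimulated gene passed among 22 (adjusted p = 0.944), adjusted over the list alone as well.

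Markers of other cell types were higher in the same nonclassical libraries. B cell genes rose in 11 of 12 cases (11 adjusted over the list alone; adjusted p = 8.13e-19, and adjusted p = 0.0681 with an estimated correlation), including Ms4a1, which encodes CD20 (8.12, SE 0.405). Tissue macrophage genes rose in 6 of 12 (9 adjusted over the list alone; adjusted p = 5.32e-09, and adjusted p = 0.0681 with an estimated correlation) and dendritic cell genes in 8 of 16 (11 adjusted over the list alone; adjusted p = 4.55e-09, and adjusted p = 0.0681 with an estimated correlation). Mast cell, basophil and eosinophil genes rose in 5 of 10 (6 higher and 1 lower adjusted over the list alone; adjusted p = 5.67e-05, and adjusted p = 0.334 with an estimated correlation). The basophil protease Prss34 stood at 2920 ± 2370 CPM against 8.27 ± 5.3 in classical monocytes. Stromal and endothelial genes rose in 2 of 11 (2 adjusted over the list alone; adjusted p = 0.000821, and adjusted p = 0.404 with an estimated correlation). The 2 nonclassical libraries correlated with r = 0.775 across genes and the 2 classical ones with r = 0.984. Leaving out classical replicate 1 or 2 gave 0 changed genes, leaving out nonclassical replicate 2 gave 195 and leaving out intermediate replicate 2, which shares the estimate of spread, gave 382.

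Intermediate monocytes were compared with classical monocytes in the same fit. C1qb rose by 8.14 (SE 0.33) to 303 ± 38.7 CPM (n = 2 libraries), Cd300e by 8.77 (SE 0.631) and H2-Eb1, an MHC class II chain, by 6.14 (SE 0.207), from 38.4 ± 4.42 to 2600 ± 55 CPM. Ly6c2 fell by 4.67 (SE 0.324) to 102 ± 32.7 CPM, F13a1 by 4.47 (SE 0.382) and Ccr2 by 1.65 (SE 0.213), while Nr4a1 rose by 1.79 (SE 0.152). Kit rose by 7.88 (SE 0.826) and Gata2, a transcription factor of progenitors and mast cells, by 7.9 (SE 0.909), and Prss34 stood at 4050 ± 2000 CPM. Of 13944 genes 294 changed (3018 at an unadjusted p under 0.05), 166 upward and 128 downward.

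Nonclassical genes rose in 12 of 20 cases (16 adjusted over the list alone; adjusted p = 1.01e-15, and adjusted p = 0.0781 with an estimated correlation) and MHC class II genes in 10 of 16 (11 adjusted over the list alone; adjusted p = 1.49e-12, and adjusted p = 0.0747 with an estimated correlation). Among lists of other cells, B cell genes rose in 10 of 12 cases (11 adjusted over the list alone; adjusted p = 6.41e-16, and adjusted p = 0.0563 with an estimated correlation), Cd79a by 5.33 (SE 0.26). Progenitor regulators rose in 6 of 18 (9 adjusted over the list alone; adjusted p = 2.73e-09, and adjusted p = 0.0563 with an estimated correlation). Tissue macrophage genes rose in 6 of 12 (10 adjusted over the list alone; adjusted p = 4.24e-10, and adjusted p = 0.0563 with an estimated correlation). Dendritic cell genes rose in 5 of 16 (9 adjusted over the list alone; adjusted p = 2.46e-09, and adjusted p = 0.0563 with an estimated correlation). Erythroid and megakaryocyte genes rose in 2 of 12 (8 higher and 1 lower adjusted over the list alone; adjusted p = 4.91e-05, and adjusted p = 0.0781 with an estimated correlation). Stromal and endothelial genes rose in 1 of 11 (3 adjusted over the list alone; adjusted p = 6.54e-05, and adjusted p = 0.266 with an estimated correlation). T and NK cell genes rose in 2 of 15 (2 adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.336 with an estimated correlation). Mast cell, basophil and eosinophil genes rose in 3 of 10 (7 adjusted over the list alone; adjusted p = 1.63e-08, and adjusted p = 0.212 with an estimated correlation). Cell cycle genes fell in 5 of 26 (11 adjusted over the list alone; adjusted p = 1.06e-07, and adjusted p = 0.258 with an estimated correlation), Mki67 by 1.42 (SE 0.202). Mpo had 5820 ± 3810 CPM against 310 ± 98.5 in classical monocytes and did not pass (adjusted p = 0.0734). Leaving out classical replicate 1 or 2 or intermediate replicate 2 gave 0 changed genes, leaving out intermediate replicate 1 gave 14 and leaving out nonclassical replicate 2 gave 96.

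Nonclassical and intermediate monocytes were compared in turn. Ly6c2 stood at 21.1 ± 5.72 CPM in nonclassical and 102 ± 32.7 CPM in intermediate libraries (n = 2 each; log2 fold change −2.3, SE 0.292), and Nr4a1 at 3870 ± 628 and 1590 ± 53.6 CPM (1.26, SE 0.149). Cd79b, a chain of the B cell receptor, had a log2 fold change of 2.02 (SE 0.213) and Top2a, the topoisomerase of dividing cells, one of −1.91 (SE 0.17). No gene of 13944 passed with edgeR (1710 at an unadjusted p under 0.05), while DESeq2 called 1205. Adjusted over the list alone, 16 of 26 cell cycle genes passed downward, 7 of 11 primary granule genes passed downward, and 11 of 12 B cell genes and 11 of 20 nonclassical genes passed upward, against 0 in each list over all genes. The camera adjusted p was 1.5e-16 for the cell cycle, 1.24e-09 for primary granules, 1.86e-14 for B cells and 8.38e-10 for nonclassical genes. With an estimated correlation none held (adjusted p = 0.275, 0.275, 0.164 and 0.275 with an estimated correlation, in that order).

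**Figure D3:**
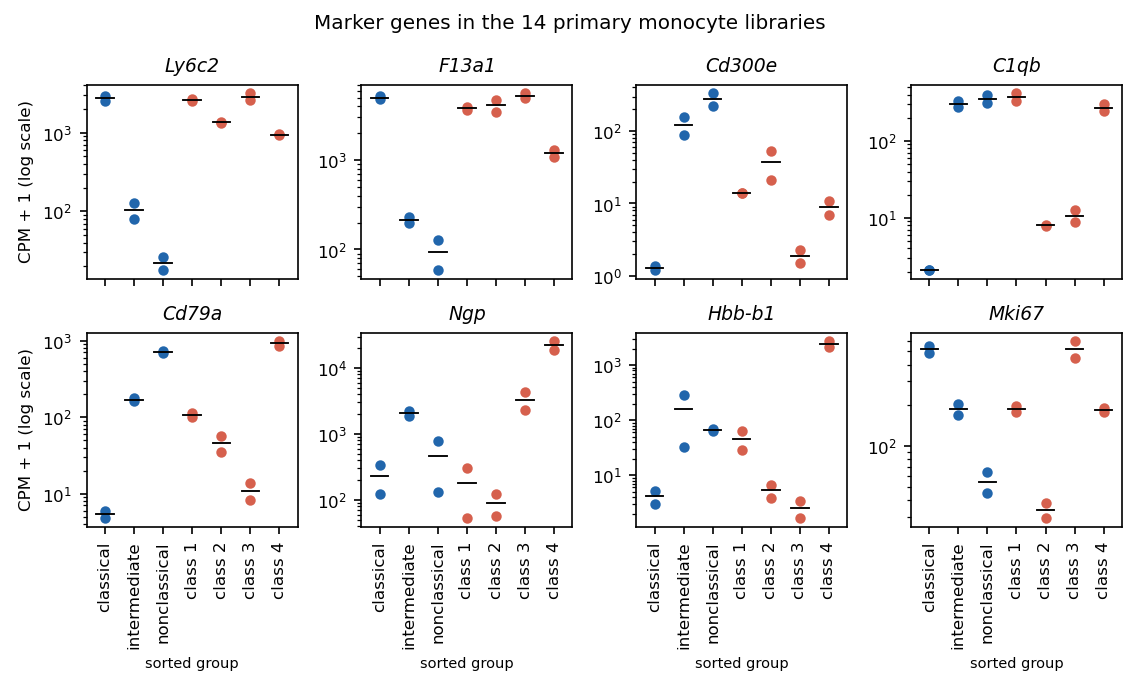
Expression of 8 marker genes in the 14 primary libraries (points; CPM plus 1 on a log axis; bars are the mean of the 2 libraries per sorted group). Ly6c2 is 21.1 CPM in nonclassical and 2720 CPM in classical monocytes, Hbb-b1 reaches 2400 CPM in class 4, and Mki67 is 32.8 CPM in class 2 and 521 CPM in class 3.

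The 4 classes were each compared with the mean of the other 3 to find what sets them apart, and 5994 of 13686 tested genes differed among them. In class 1, Irf7, a transcription factor of the interferon response, rose by 2.87 (SE 0.131), with 958 ± 1.86 CPM in class 1 and 380, 57.2 and 96.4 CPM in classes 2 to 4 (n = 2 libraries per class). C1qb rose by 3.79 (SE 0.16), with 371 ± 61.8 CPM in class 1, 6.99 and 9.67 CPM in classes 2 and 3, and 270 CPM in class 4. Ly6i (4.17, SE 0.285), Ly6a (3.5) and Serpina3g (3.81, SE 0.237) were among the 6 strongest increases. Pglyrp1, a bactericidal granule protein, fell by 2.26 (SE 0.225) and Cebpe, a transcription factor of granulocytes, by 2.19. Csf1r rose by 1.4 (SE 0.116), and Mpo fell by 1.23 (SE 0.229).

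In class 1, 880 genes were higher and 202 lower (1082 in all; 3056 at an unadjusted p under 0.05). Interferon-stimulated genes rose in 19 of 22 cases (22 adjusted over the list alone; adjusted p = 1e-58, and 0.0244 with an estimated correlation), Ifit3 by 3.15 (SE 0.152). Tissue macrophage genes rose in 9 of 12 (10 adjusted over the list alone; adjusted p = 8.45e-44, and 0.0244 with an estimated correlation), and genes of monocyte differentiation in 12 of 20 (17 adjusted over the list alone; adjusted p = 1.35e-18, and 0.0297 with an estimated correlation). Inflammatory genes rose in 7 of 17 (11 adjusted over the list alone; adjusted p = 1.31e-09, and 0.0244 with an estimated correlation), Ccl5, a chemokine, by 3.56. MHC class II genes rose in 10 of 16 (12 adjusted over the list alone; adjusted p = 2.31e-22, and adjusted p = 0.0634 with an estimated correlation), H2-Eb1 by 2.97 (SE 0.316). Cell cycle genes rose in 15 of 26 (22 adjusted over the list alone; adjusted p = 8.95e-18, and adjusted p = 0.0655 with an estimated correlation). The mean they were set against takes in class 2, where these genes were very low, and Ccnb1 and Plk1 were lower in class 1 than in class 3. T and NK cell genes rose in 5 of 15 (11 adjusted over the list alone; adjusted p = 6.95e-07, and adjusted p = 0.102 with an estimated correlation). Neutrophil genes fell in 11 of 19 (16 adjusted over the list alone; adjusted p = 2.51e-19, and adjusted p = 0.0846 with an estimated correlation), against a mean that takes in class 4, where they were higher. The number of genes changed in class 1 became 216 or 281 when replicate 1 or 2 of class 1 itself was left out, 615 or 703 when that of class 2 was, 701 or 541 when that of class 3 was and 2188 or 1763 when that of class 4 was.

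Cell cycle genes were low in class 2. Ccnb1, cyclin B1, was at 8.54 ± 0.0229 CPM (n = 2) against 179, 454 and 144 CPM in classes 1, 3 and 4, and Plk1, a mitotic kinase, at 7.93 ± 0.3 CPM against 196, 446 and 164 CPM. Granule genes of precursors fell, Mpo by 5.51 (SE 0.302) and the protease gene Ctsg by 5.62 (SE 0.289). Of the nonclassical list, Ace, the angiotensin-converting enzyme, rose by 4.75 (SE 0.505), Cx3cr1 by 2.53 (SE 0.132) and Nr4a1 by 2.03 (SE 0.137), the last to 1320 ± 178 CPM, while Ly6c2 fell by 0.43. Slfn5, an interferon-inducible gene, rose by 3.33 (SE 0.177) and S1pr5, a receptor for sphingosine phosphate, by 3.34 (SE 0.439).

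The comparison gave 2281 higher and 1787 lower genes (4068 in all). All 26 cell cycle genes fell (26 adjusted over the list alone; adjusted p = 1.11e-101, and 0.0184 with an estimated correlation), as did all 11 primary granule genes (11 adjusted over the list alone; adjusted p = 1.15e-26, and adjusted p = 0.0569 with an estimated correlation). Nonclassical genes rose in 16 of 20 cases (17 adjusted over the list alone; adjusted p = 1.18e-11, and adjusted p = 0.125 with an estimated correlation). Classical genes rose in 11 of 16 and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 5e-06, and adjusted p = 0.113 with an estimated correlation). Immediate early and heat shock genes rose in 11 of 16 (11 adjusted over the list alone; adjusted p = 0.000125, and adjusted p = 0.349 with an estimated correlation). Interferon-stimulated genes rose in 20 of 22 (21 adjusted over the list alone; adjusted p = 2.21e-12, and adjusted p = 0.103 with an estimated correlation) and pattern recognition receptors in 12 of 17 (13 adjusted over the list alone; adjusted p = 4.71e-07, and adjusted p = 0.0591 with an estimated correlation). Mast cell, basophil and eosinophil genes fell in 8 of 12 (8 adjusted over the list alone; adjusted p = 4.24e-05, and adjusted p = 0.0846 with an estimated correlation), and Prss34 was listed at 0 in both class 2 libraries against 1040 ± 496 CPM in class 4. T and NK cell genes fell in 10 of 15 (14 adjusted over the list alone; adjusted p = 4.24e-05, and adjusted p = 0.157 with an estimated correlation). Erythroid and megakaryocyte genes fell in 9 of 14 (9 adjusted over the list alone; adjusted p = 4.97e-06, and adjusted p = 0.16 with an estimated correlation). B cell genes fell in 7 of 12 (7 adjusted over the list alone; adjusted p = 0.00495, and adjusted p = 0.349 with an estimated correlation). Tissue macrophage genes fell in 7 of 12 and rose in 2 (7 and 2 adjusted over the list alone; adjusted p = 7.81e-07, and adjusted p = 0.113 with an estimated correlation). Neutrophil genes fell in 10 of 19 and rose in 4 (10 and 4 adjusted over the list alone; adjusted p = 0.00495, and adjusted p = 0.436 with an estimated correlation). The mean that class 2 was set against takes in class 4, where these lists of other cells were higher. Hbb-b1, for example, was not lower in class 2 than in class 3. The lists were not tested between single classes. Leaving out class 2 replicate 1 or 2 gave 2240 or 2060 changed genes.

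In class 3, Ccnb1 rose by 2.9 (SE 0.0899), to 454 ± 27.5 CPM (n = 2), Plk1 by 2.8 (SE 0.128) and Iqgap3, a scaffold protein of dividing cells, by 3.61 (SE 0.146). Mpo rose by 2.88 (SE 0.192), to 3760 ± 685 CPM, Ctsg by 3.11 (SE 0.182) and Elane, neutrophil elastase, by 2.98 (SE 0.28), and Ly6c2 rose by 0.93 (SE 0.1). Il1b, interleukin-1 beta, fell by 5.59 (SE 0.394), H2-Eb1 by 4.66 (SE 0.473), Ifit3 by 4.62 (SE 0.23) and Nr4a1 by 2.58 (SE 0.177).

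For class 3, 1553 genes were higher and 1339 lower (2892 in all). Cell cycle genes rose in 25 of 26 cases (26 adjusted over the list alone; adjusted p = 2.5e-82, and 0.0288 with an estimated correlation) and primary granule genes in 10 of 11 (10 adjusted over the list alone; adjusted p = 4.81e-17, and 0.0376 with an estimated correlation). Interferon-stimulated genes fell in 21 of 22 (21 adjusted over the list alone; adjusted p = 1.37e-27, and 0.0376 with an estimated correlation), inflammatory genes in 11 of 17 (11 adjusted over the list alone; adjusted p = 2.75e-11, and 0.0288 with an estimated correlation) and pattern recognition receptors in 11 of 17 (11 adjusted over the list alone; adjusted p = 4.5e-07, and 0.0432 with an estimated correlation). Nonclassical genes fell in 17 of 20 and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 2.49e-14, and adjusted p = 0.0872 with an estimated correlation). The classical list did not pass (3 of 16 higher and 5 lower, 3 and 7 adjusted over the list alone; adjusted p = 0.119). Immediate early and heat shock genes fell in 7 of 16 (7 adjusted over the list alone; adjusted p = 0.000863, and adjusted p = 0.432 with an estimated correlation). Among markers of other cells, tissue macrophage genes fell in 10 of 12 (11 adjusted over the list alone; adjusted p = 2.84e-18, and 0.0376 with an estimated correlation) and B cell genes in 12 of 12 (12 adjusted over the list alone; adjusted p = 1.62e-23, and adjusted p = 0.0575 with an estimated correlation). The mean that class 3 was set against takes in class 4, where both lists were higher. Mast cell, basophil and eosinophil genes rose in 4 of 12 (5 adjusted over the list alone; adjusted p = 0.00387, and adjusted p = 0.108 with an estimated correlation). Neutrophil genes went both ways, 7 of 19 higher and 6 lower (10 and 6 adjusted over the list alone; adjusted p = 0.838). Leaving out class 3 replicate 1 or 2 gave 1376 or 1095 changed genes.

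Class 4 carried genes of several other blood lineages. The globin gene Hbb-b1 rose by 8.48 (SE 0.414), with 2400 ± 425 CPM (n = 2) against 45.3, 4.3 and 1.53 CPM in classes 1 to 3, and Car2, a carbonic anhydrase of red cell precursors, rose by 6.48 (SE 0.246). Ngp rose by 5.86 (SE 0.558), to 22100 ± 4540 CPM, and Retnlg, a secreted neutrophil protein, by 7.62 (SE 0.597). Vpreb3, a pre-B cell gene, rose by 5.77 (SE 0.278), with 329 ± 60.7 CPM against 15.4, 5.87 and 2.31 CPM. Of the monocyte genes named in advance, Csf1r fell by 2.71 (SE 0.148) to 250 ± 21.1 CPM, Cx3cr1 by 3.17 (SE 0.179) and Ly6c2 by 1.21 (SE 0.113). Mpo rose by 3.86 (SE 0.193) and Kit by 2.91.

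In class 4, 2799 genes were higher and 2649 lower (5448 in all). Erythroid and megakaryocyte genes rose in 12 of 14 cases (12 adjusted over the list alone; adjusted p = 2.93e-34, and 0.046 with an estimated correlation) and B cell genes in 11 of 12 (11 adjusted over the list alone; adjusted p = 3.76e-33, and 0.0483 with an estimated correlation). Neutrophil genes rose in 17 of 19 (17 adjusted over the list alone; adjusted p = 8.33e-21, and adjusted p = 0.0918 with an estimated correlation). Mast cell, basophil and eosinophil genes rose in 10 of 12 (12 adjusted over the list alone; adjusted p = 1.35e-10, and adjusted p = 0.053 with an estimated correlation), and T and NK cell genes in 12 of 15 (13 adjusted over the list alone; adjusted p = 8.52e-07, and adjusted p = 0.0996 with an estimated correlation). Tissue macrophage genes rose in 9 of 12 (11 adjusted over the list alone; adjusted p = 1.11e-14, and adjusted p = 0.0514 with an estimated correlation). Cell cycle genes rose in 23 of 26 (24 adjusted over the list alone; adjusted p = 8.66e-10, and adjusted p = 0.103 with an estimated correlation). Here too the mean takes in class 2, where these genes were very low. Ccnb1 and Plk1 were lower in class 4 than in class 1 or class 3. All 11 primary granule genes rose (11 adjusted over the list alone; adjusted p = 2.85e-29, and 0.046 with an estimated correlation), as did 12 of 17 ribosome biogenesis genes (13 adjusted over the list alone; adjusted p = 8.52e-07, and 0.046 with an estimated correlation). Genes of monocyte differentiation fell in 19 of 20 cases (20 adjusted over the list alone; adjusted p = 1.44e-16, and 0.046 with an estimated correlation) and lysosomal genes in 17 of 22 (20 adjusted over the list alone; adjusted p = 2.03e-12, and adjusted p = 0.0996 with an estimated correlation).

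**Figure D4:**
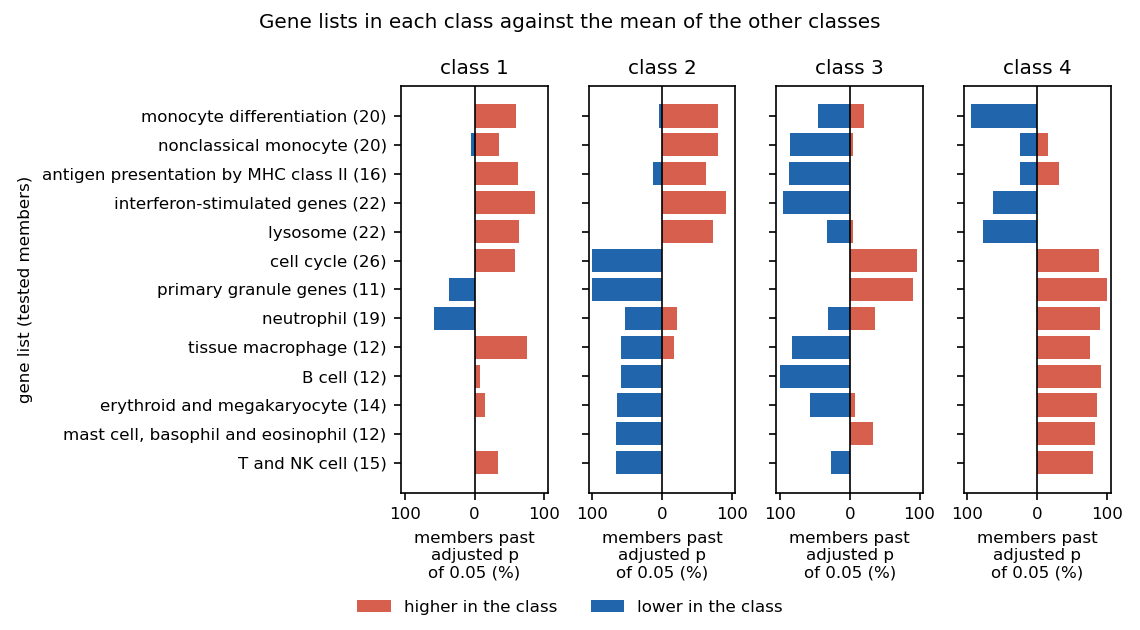
Share of the tested members of 13 gene lists (in percent, number tested in brackets) that were higher or lower in each class than in the mean of the other 3 classes at an adjusted p under 0.05. All 26 cell cycle genes are lower in class 2 and 25 of 26 higher in class 3, and 12 of 14 erythroid and megakaryocyte genes are higher in class 4.

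Between single classes, class 4 against class 2 gave the highest number of changed genes, 5604, and class 2 against class 1 the lowest, 1272. The others gave 1831 for class 3 against class 1, 3442 for class 4 against class 1, 3310 for class 3 against class 2 and 3917 for class 4 against class 3. Leaving out class 1 replicate 1 or 2 gave 554 or 495 genes for class 2 against 1, 725 or 819 for class 3 against 1 and 1546 or 1719 for class 4 against 1. Leaving out class 2 replicate 1 or 2 gave 572 or 622 for class 2 against 1 and 2145 or 2170 for class 3 against 2, and leaving out class 2 replicate 2 gave 3487 for class 4 against 2. Leaving out class 3 replicate 1 or 2 gave 888 or 615 for class 3 against 1, 1934 or 1922 for class 3 against 2 and 2017 or 1798 for class 4 against 3. Leaving out class 4 replicate 1 or 2 gave 2325 or 2312 for class 2 against 1 and 2942 or 2944 for class 3 against 1.

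To relate classes and subsets, the 100 genes with the smallest p among those higher in nonclassical monocytes, and the 100 among those higher in classical monocytes, were tested in the class libraries. These lists come from other libraries than those tested. In class 3, 79 of the 100 classical-high genes were higher and none lower (adjusted p = 7.29e-95, and 0.00175 with an estimated correlation), and 85 of the 100 nonclassical-high genes were lower and none higher (adjusted p = 1.47e-58, and 0.0479 with an estimated correlation). In class 2, 56 classical-high genes were lower and 25 higher (adjusted p = 1.3e-43, and 0.00322 with an estimated correlation), and the nonclassical-high genes went both ways, 35 higher and 30 lower (adjusted p = 0.961; the median was −0.36 with camera downward). In class 1, 37 classical-high genes were higher and 6 lower (adjusted p = 1.11e-09, and 0.0479 with an estimated correlation), and 29 nonclassical-high genes were higher and 1 lower (adjusted p = 1.36e-19, and adjusted p = 0.155 with an estimated correlation). In class 4, 64 nonclassical-high genes were higher and 7 lower (adjusted p = 4.93e-31, and adjusted p = 0.099 with an estimated correlation), and the classical-high genes did not pass (32 higher, 39 lower, adjusted p = 0.084). With 50 genes per list the classical-high genes in class 1 (16 higher, 2 lower) kept their median of 0.39 and their preset call (adjusted p = 5.86e-07) but not the other (adjusted p = 0.0785 with an estimated correlation), and the nonclassical-high genes in class 2 had camera upward (adjusted p = 0.577) with a median of −0.55. The nonclassical libraries from which the list was drawn also had more B cell, macrophage and basophil transcripts than the classical ones. Their marker lists passed camera at the preset correlation but not with an estimated one. Of 26 cell cycle genes, 13 were higher in the classical libraries (adjusted p = 0.118 with an estimated correlation). The classical monocyte list fixed in advance did not move with the classical-high genes, with a median of −0.26 in class 3 and 1.03 in class 2.

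Scores of the genes higher in each class were finally compared between the progenitor and monocytic libraries over the 24 clones, since the labels put no clone in a class. None of the 4 correlations passed (0 at an unadjusted permutation p under 0.05, and 0 with Spearman's rho). Class 1 genes gave r = 0.35 (permutation p = 0.0936, adjusted p = 0.219; rho = 0.4, permutation p = 0.0516) and class 4 genes r = 0.33 (permutation p = 0.109, adjusted p = 0.219; rho = 0.22, permutation p = 0.296). Class 2 genes gave r = 0.17 (permutation p = 0.426, adjusted p = 0.528; rho = 0.1, permutation p = 0.642) and class 3 genes r = 0.13 (permutation p = 0.528, adjusted p = 0.528; rho = −0.01, permutation p = 0.983). Without the 2 farthest clones r was 0.43, 0.07, −0.19 and 0.24 for classes 1 to 4. In clones 1 to 13 it was 0.25, 0.5, −0.36 and −0.44, and in clones 15 to 25 it was 0.33, 0.33, 0.01 and −0.26.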

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

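The interaction term between clone set and state and the test of a batch shared by each clone set were chosen only after the data had been seen. The change from progenitor to monocytic cells differed between clones 1 to 13 and clones 15 to 25 in 2755 genes (interaction term in edgeR). For 2007 of them the signed log2 change was higher in clones 1 to 13. This count goes by sign, so a gene that fell further in clones 15 to 25 is counted too. Lyz1, for example, rose by 8.97 in clones 1 to 13 and by 4.11 in clones 15 to 25, and Itgam, an integrin of phagocytes, by 7.17 and 4.81. Of 5432 genes that changed in both sets, 5324 moved the same way. The state labels were also swapped at random within clones. Of 30 splits, the real one included, 1 gave as many as the 9132 genes changed between the states, and the highest of the others gave 0. Swapping turns the state difference into spread between clones, which lowers the number of calls by itself. The splits therefore speak only to the total number of calls and do not exclude chance for single genes.

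The progenitors of a clone resembled their own monocytic cells, with a mean correlation of 0.236 against 0.006 for permuted pairings. A batch that follows the 2 clone sets as drawn here was not the whole cause, since the mean was 0.193 (permutation p = 1e-05, the smallest possible) when each library was centred on its own set and state. Nor was library depth, as the set-centred mean was 0.156 (permutation p = 2e-05) over 23 clones, with clone 21 left out and every other library thinned to 1.83 M counts, nor whole-chromosome copy number, as removing each library's chromosome medians left 0.192 (permutation p = 1e-05). The sets may also be drawn wrongly for single libraries. On the second principal component the progenitors of clones 1 to 13 were all negative. Those of clones 15 to 25 were positive, except the clone 24 progenitors (−18.4). Centring on these sets cannot remove a batch with another boundary. That clone differences persist through maturation is a hypothesis, which no test here decides. The resemblance was more evident in clones 15 to 25 (0.343) than in clones 1 to 13 (0.066), a difference that was not itself tested. The labels do not say which animal a clone came from or whether the libraries of a clone were prepared together, so inherited differences between donors and handling shared within a clone stay open and untested. On the first principal component, which parts the states, monocytic libraries of clones 15 to 25 ran from −2.28 (clone 22, with Mpo as top gene) to 157 (clone 20). Clone 20 was also the highest among the progenitors (−28.1). The resemblance was not separated from how far each clone had matured.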

How the results depend on the processing

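The separate fits of clones 1 to 13 and clones 15 to 25, the set-centred correlations and the clone set by state term were chosen after seeing the data; the other settings were planned. DESeq2 size factors in edgeR, a minimum count of 50 and a prior count of 0.5 moved no main count by over 1.5 times, and size factors shifted the median change of no comparison by over 0.068. For the named genes, 2421 of 2588 values under other settings kept direction and call. Where counts moved, the cause was not tested, except that fewer samples leave fewer degrees of freedom. Clones 15 to 25 alone gave 6070 genes changed with state, and no filter gave 7654 changed at least 2-fold. The clone effect took in 2054 genes with no filter, 4122 by the DESeq2 likelihood ratio test, 36 in clones 1 to 13, 387 in clones 15 to 25 and 763 with a clone set by state term. With DESeq2, 3357 genes changed between nonclassical and classical, 3093 between intermediate and classical and 1205 between nonclassical and intermediate monocytes, and with 1 fit over all 14 primary libraries 2742, 2331 and 624. That fit gave 3500 genes among classes, 411, 2453, 1623 and 3357 for classes 1 to 4 against the others, and 572, 888, 1722, 2005, 3357 and 1993 for class 2 against 1, 3 against 1, 4 against 1, 3 against 2, 4 against 2 and 4 against 3. Class 1 had 2167 genes with no filter and 1799 with DESeq2, class 2 against 1 had 2325 and 2215, and class 3 against 1 had 2785 with DESeq2. Correlated genes numbered 423 with Spearman's rho, 106 on residuals of the log2 total, 0 in clones 1 to 13, 71 in clones 15 to 25 and 133 centred on the set. Correlated list scores numbered 2, 1, 0, 2 and 2 in that order. Of 146 list calls among 207 tests, 18 held with an estimated correlation. Leaving out single libraries gave 0 to 869 genes for nonclassical and 0 to 205 for intermediate against classical monocytes, 216 to 2188 for class 1, 2060 to 5295 for class 2, 1095 to 4000 for class 3, 495 to 2325 for class 2 against 1, 615 to 2944 for 3 against 1, 1546 to 4305 for 4 against 1, 1922 to 4342 for 3 against 2, 3487 to 6099 for 4 against 2 and 1798 to 4704 for 4 against 3; a lone library was assumed to vary like the other groups. Directions turned for Mki67 between states (−0.43 in clones 15 to 25, not past the test either way), for the correlation of Malat1 (−0.41 in clones 1 to 13 and −0.28 centred on the set) and for that of Padi4 (−0.17 in clones 1 to 13). Correlations that had not passed turned for Csf1r (−0.1 in clones 15 to 25), Kit (−0.09 in clones 1 to 13), Nr4a1 (−0.06 in clones 1 to 13) and Cx3cr1 (−0.26 in clones 15 to 25), and of the list scores that passed, erythroid (−0.56) and NADPH oxidase (−0.07) turned in clones 1 to 13. With a block on the replicate number 670 and 263 genes changed between nonclassical or intermediate and classical monocytes, and 0 between nonclassical and intermediate monocytes, though the labels do not say that the numbers pair libraries; replicate differences of these groups correlated with r of 0.18, 0.281 and 0.384 across genes. Depth limits most the progenitors of clone 21, without which 881 genes correlated between states.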

Other observations

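Apart from the class 4 lists, which were fixed in advance, the genes and tests in this part, the definition of on-or-off genes included, were chosen after the data had been seen. In 91 genes the progenitor libraries fell into a high and a low set of clones, with a gap of at least 2 on the log2 CPM scale and at least 3 clones on each side. The monocytic libraries were only ranked: as many of the highest were counted as high as there were high progenitor libraries, and no gap was required. By this ranking, 79.9% of the clones' levels were on the same side in their monocytic cells. Permuted pairings gave 61.7%, and pairings permuted within clone sets 70% (permutation p = 1e-05 in both cases, the smallest they can give). Monocytic levels need not form 2 sets: Timp2 averaged 6.49 in the monocytic cells of its progenitor-high clones and 7.78 in the others. In 8 genes all 24 clones kept their side, and for Gm13436, 1 of them, the sides were the 2 clone sets themselves. Mtus2, which encodes a microtubule-binding protein, averaged 3.92 in 15 clones and −2.34 in 9 clones as progenitors, and 3.91 and −2.27 in the monocytic cells of the same clones. Tfpi, the inhibitor of the tissue factor pathway of coagulation, averaged 5.87 and −1.8 in progenitors and 3.47 and −2.66 in monocytic cells, with 10 clones on the high side. Clec11a, a secreted growth factor of the marrow, was high in exactly the 12 clones in which Tmem223, a mitochondrial membrane protein gene, was low. Arap2 and Efna5, the latter a ligand of Eph receptors, were both low in clones 15, 16, 18, 19, 20 and 21 and in no other clone.

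Same-clone pairing was repeated on the most variable genes of each set. With 50 genes the mean same-clone correlation was 0.53 in clones 1 to 13, with 8 of 13 progenitor libraries closest to their own monocytic library, and 0.751 in clones 15 to 25, with 11 of 11 (permutation p = 1e-05 in each set). With 200 genes the values were 0.37 (7 of 13) and 0.68 (11 of 11), and with 1000 genes 0.187 (6 of 13) and 0.535 (11 of 11).

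Genes on chromosome 17 were higher in both libraries of clone 25 than in the mean of the other clones of its set. Of 596 tested chromosome 17 genes 73.3% were above this mean in both libraries, with medians of 0.59 and 0.58 on the log2 scale, against 58% of 646 on chromosome 1, which was raised as well (medians 0.34 and 0.36), and 27.1% of 920 on chromosome 2. With each library centred on its clone set, the chromosome 17 median stood at 0.539 and 0.529 in clone 25, but also at 0.517 in the monocytic library of clone 9, whose progenitors were at −0.046. An extra copy of chromosome 17 is a candidate explanation, which would raise nearly every gene (bound set at 80%), while a few raised genes would leave under 60%. The value lies between these bounds. The bounds ask for both libraries at once and make no allowance for noise of single genes, so they cannot decide the question. In single libraries of clone 25, 85.6% of the chromosome 17 genes were above the mean in the progenitors and 78.5% in the monocytic cells.

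In class 4, camera called lists of 5 other blood lineages higher. With an estimated correlation B cell (0.0483) and erythroid genes (0.046) held, while neutrophil, mast cell and T and NK cell genes did not (adjusted p = 0.0918, 0.053 and 0.0996 with an estimated correlation). The most abundant gene of each reached 916 CPM for Cd79a, 2400 for Hbb-b1, 22100 for Ngp, 1040 for Prss34 and 84.6 for Cd2. Of 19 neutrophil genes 4 stand in another list too, and classical monocytes had at least 1 CPM of 16 neutrophil, 10 B cell, 3 erythroid, 2 mast cell and basophil and 0 T and NK cell genes. Neither the gates of the sort nor the definition of class 4 are given, and the cause was not tested.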
